A study of Mus musculus with 16 samples.

How the data were processed

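Whole-brain RNA of 16 female mice aged 6 months was measured with a neuropathology panel on a digital counting platform (nCounter), with 4 wild type, 4 Grn knockout, 4 Trem2 knockout and 4 Grn and Trem2 double knockout animals, per the labels. RNA was purified with a silica column kit (RNeasy Mini), per the labels' protocols. Genotype came from each sample's label, and each sample carried an animal number of its own. Replicate numbers follow the order of deposit and pair no animals. Cartridge, lane and run day are not given in the sources used here.

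The deposited table holds a signal per probe for 770 panel genes, 6 positive and 8 negative control probes in each animal. The software, the background correction and the normalization the authors used are not given in the sources used here, so the scaling was read from the values. At least 99.74% of the gene values in each animal are whole multiples of 1 step, within a tolerance of 0.0075 counts, so the deposited signal is a whole count multiplied by 1 factor per animal (0.907 to 1.36). The geometric mean of 10 reference genes (Aars, Asb7, Ccdc127, Cnot10, Csnk2a2, Fam104a, Lars, Mto1, Supt7l and Tada2b) is equal in all animals at 321.56, with an SD of 6.63e-06 in mean log2 value, so the deposited values are scaled to these genes. No background was subtracted, and the control probes are unscaled whole counts. A gene that moved with the reference genes would be hidden by this scaling. Background adds to weak genes, and where it is equal in 2 groups it understates their fold changes. It was not equal: scaled negative controls averaged 18.3 in wild type, 13.4 in the Grn knockout, 14.2 in the Trem2 knockout and 14.7 in the double knockout. Falls of weak genes against wild type can therefore be overstated. All 770 gene symbols were found in a RefSeq gene table of assembly GRCm38.p6, 763 as symbol and 7 as synonym; the table was used for names only.

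Division by the factor gave 477113 to 767742 gene counts per animal, with group means of 651280.0 in wild type, 630361 in the Grn knockout, 623082 in the Trem2 knockout and 656428 in the double knockout. The 10 most abundant genes held 14.7% to 16.3% of the counts. Negative controls averaged 17.3 counts per probe in wild type, 12.4 in the Grn knockout, 13.0 in the Trem2 knockout and 13.8 in the double knockout. Sums of the positive controls ran from 17588 to 45949, with group means of 36423 ± 11369.7 in wild type, 27302 ± 7977 in the Grn knockout, 28731 ± 7846 in the Trem2 knockout and 27764 ± 7999 in the double knockout. The background threshold of an animal was the mean plus 2 SD of its negative controls, on the scale of the deposited values. Fold changes of the knocked-out genes are lower bounds against that threshold or the measured value, whichever was higher in each animal. All 24 pairs of animals within a group differed by more than counting noise (chi-square per degree of freedom 3.44 to 17.07), so none was counted as a repeat of another.

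Genes with a mean of at least 20 over the 16 animals were tested (708; 62 were not). Values were taken as log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 4 group means and 12 residual degrees of freedom in 1 fit. The tests were two-sided, with Benjamini-Hochberg adjustment over genes within each comparison and a threshold of 0.05. The comparisons were each knockout against wild type, the double knockout against each single knockout, and the interaction. Gene lists were tested with limma's fry, whose directional p asks whether the members move, on balance, one way; it compares a list with no other genes. Adjustment was over 17 lists within a comparison. The lists were homeostatic microglia, activated microglia, lysosome, complement, cytokine and innate signalling, astrocyte, reactive astrocyte, oligodendrocyte and myelin, pan-neuronal, glutamatergic synapse, GABAergic, dopamine and striatum, endothelium and mural cells, cholesterol and lipid handling, autophagy, oxidative stress and immediate early genes. The 12 housekeeping genes measured served as a control list. Lists with fewer than 5 tested members (interferon and antigen presentation, oligodendrocyte precursor, and peripheral leukocyte) had no list test. Of a choroid plexus list 0 genes were tested. Grn and Trem2 were left out of every list. Single values were compared by two-sided exact permutation tests over all 70 arrangements of 4 against 4 animals, whose smallest p is 0.0286.

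The groups, comparisons, tests, lists, most of the other settings tried and the rule for naming genes were chosen before the data were examined. The rule takes Grn and Trem2, up to 12 called genes with the largest rise and 12 with the largest fall and every animal on 1 side of the other group's mean, up to 4 members of each list with the smallest adjusted p, and a fixed set of microglial, lysosomal and astrocyte genes. The text gives a part of the genes so chosen. The other settings were pseudocounts of 10 and 0, no filter or a minimum mean of 50, recentring on the median or on the housekeeping list, quantile normalization, a fit of only the groups compared, a trended and robust variance, animal weights (statmod 1.5.0), leaving out each animal in turn, camera with a preset correlation of 0.01 or an estimated one, and lists without shared members. Added after the data were seen were limma's voom on the recovered counts, scaling by the positive controls, subtraction of the negative controls, and the effect of each gene's loss averaged over both states of the other gene.

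The gene test was tested on simulated data in which 200 of 708 genes changed. At a 1.5-fold change it recovered 60 of 67 genes for Grn knockout against wild type, 57 of 67 for Trem2 knockout against wild type, 60 of 67 for double knockout against wild type, 57 of 67 for double against Grn knockout, 54 of 67 for double against Trem2 knockout and 40 of 67 for the interaction. With 6 genes changed per run, the share recovered at 1.5-fold was 62.5% for Grn knockout against wild type, 65% for Trem2 knockout against wild type, 50% for double knockout against wild type, 62.5% for double against Grn knockout, 62.5% for double against Trem2 knockout and 22.5% for the interaction. In 10 runs without change 0 genes were called. With 30 runs of Grn knockout against wild type and a log2 shift of 0.3, fry called the complement list in 13, the lysosome list in 30 and the activated microglia list in 30. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used to recover counts, compare pairs of animals, find outlying values and draw figures. The exact tests were run in R.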

Results

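Transcripts of 770 neuropathology genes were measured in whole-brain RNA of 16 female mice aged 6 months. The animals fell into 4 genotypes of 4 mice each. Wild type mice were compared with mice lacking Grn, the gene of the lysosomal and secreted protein progranulin. They were also compared with mice lacking Trem2, a lipid-sensing receptor of microglia, and with mice lacking both genes. The assay was a digital hybridization count (nCounter), in which barcoded probes are counted one by one without amplification. Between 477113 and 767742 panel counts were obtained per animal, and 655 to 714 genes lay above the negative controls. Values are normalized counts, given as mean ± SD with n = 4 unless stated. Fold changes are on the log2(value + 1) scale. The study asked whether loss of TREM2 alters the hyperactive state of progranulin-deficient microglia and the lysosomal changes that accompany progranulin loss.

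The knocked-out genes followed the labels in all 16 animals. Grn measured 617 ± 45.4 in wild type and 589 ± 34.0 in the Trem2 knockout, but 13.6 ± 4.72 in the Grn knockout and 16.9 ± 4.62 in the double knockout. All 8 animals without Grn lay below the background threshold set by the negative controls, so the transcript was at least 26.6-fold lower in the Grn knockout and at least 22.9-fold lower in the double knockout than in wild type. Trem2 measured 143 ± 13.2 in wild type, 17.3 ± 12.4 in the Trem2 knockout and 14.1 ± 6.66 in the double knockout, at least 5.19-fold and 5.31-fold lower. Trem2 knockout replicate 1, at 35.4, was the 1 such animal above its background threshold. Which part of each gene the probe covers is not given in the sources used here.

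**Figure D1:**
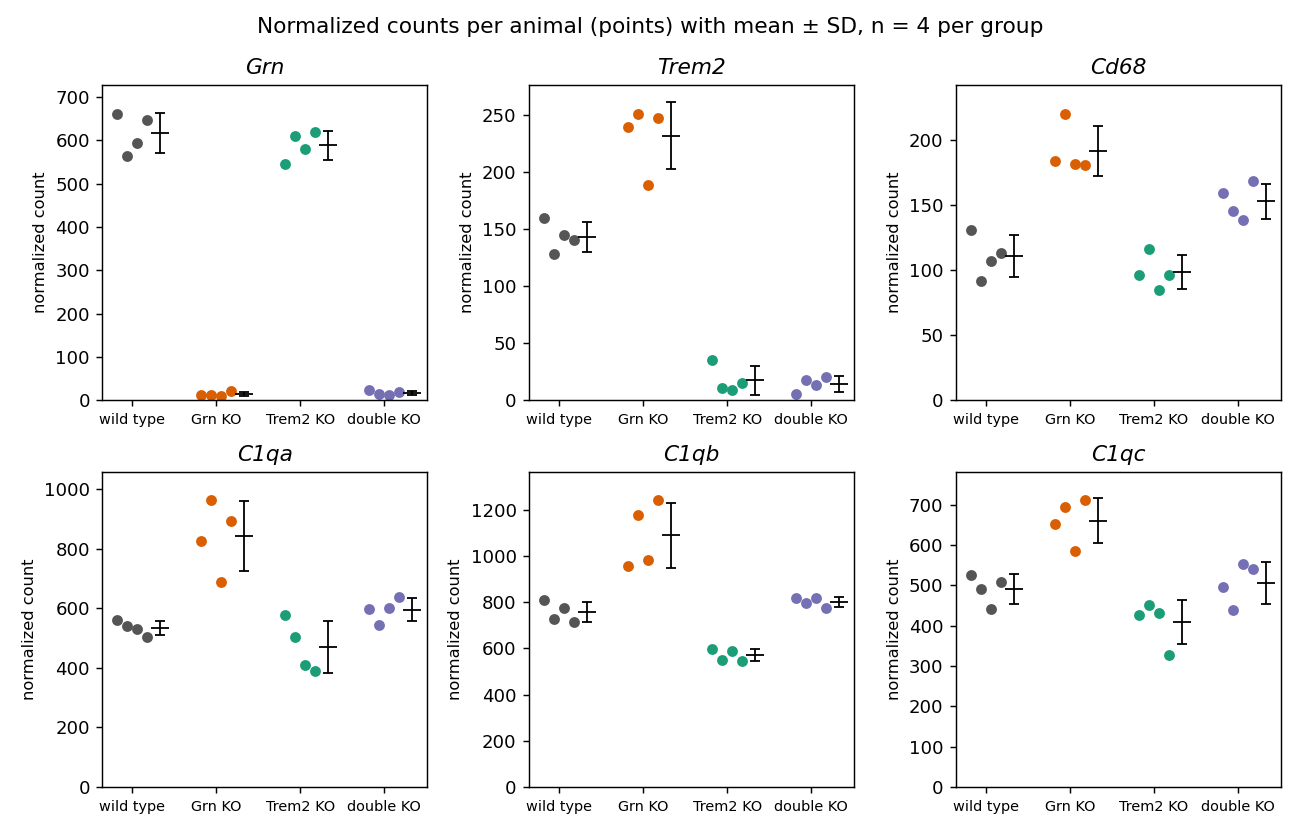
Normalized counts (vertical axis, linear scale from 0) of Grn, Trem2, Cd68, C1qa, C1qb and C1qc in each animal (points), by genotype (horizontal axis), with mean ± SD (n = 4). Cd68 and the 3 C1q chains were highest in the Grn knockout, where C1qb averaged 1090.3 against 756 in wild type and 802 in the double knockout.

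The Grn knockout was set against wild type to measure the response of the brain to progranulin loss. Cd68, a marker of phagocytic microglia, and C1qa and C1qb, chains of the complex that starts the classical complement pathway, rose. Cd68, an endosomal and lysosomal glycoprotein, went from 111 ± 16.2 to 192 ± 19.1, 1.73-fold higher (log2 fold change 0.79, SE 0.12, limma adjusted p = 0.00194). C1qa rose 1.57-fold, from 533 ± 23.8 to 843 ± 117 (limma adjusted p = 0.0144), and C1qb rose 1.43-fold, from 756 ± 43.9 to 1090.3 ± 142 (limma adjusted p = 0.00353). For each of these 3 genes, all 4 knockout animals exceeded every wild type animal.

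Of 708 genes tested with limma, 4 passed an adjusted p of 0.05, the 3 above and Grn itself, and 38 had an unadjusted p under 0.05, where 35.4 would be expected by chance. The complement list rose as a group, with all 6 members above 0, a median log2 fold change of 0.32 and a fry adjusted p of 0.00882; 2 of its members, C1qa and C1qb, passed over all genes, and 3 passed adjusted over the list alone. C1qc, the remaining C1q chain, measured 660.0 ± 56.5 against 491 ± 36.9 (log2 fold change 0.42, limma adjusted p = 0.177). It passed after recentring on the median (limma adjusted p = 0.0220) and without Trem2 knockout replicate 4 (0.0375). C4a, at 37.0 ± 9.13 against 31.3 ± 4.79, lay close to the background threshold, which ran from 16.3 to 39.1 over the 16 animals.

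The activated microglia list also rose, with 8 of 9 members above 0, a median of 0.06 and a fry adjusted p of 0.0212, but Cd68 was its 1 member past the threshold, over all genes and adjusted over the list alone. Without Cd68, the 1 tested gene it shares with the lysosome list, its fry adjusted p was 0.429. The list also lost its call without any 1 of wild type replicates 2 and 4, Grn knockout replicates 1, 2 and 4 and Trem2 knockout replicate 4, with fry adjusted p from 0.0553 to 0.0765. Apoe, which encodes an apolipoprotein, had a log2 fold change of 0.20 (limma adjusted p = 0.726). Cybb and Tlr2, an oxidase subunit and an innate receptor, both near background, had 0.45 and 0.28. Ncf1, another subunit of the same oxidase, had 0.49 (limma adjusted p = 0.496).

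Homeostatic microglia genes did not pass the test as a group (7 of 8 above 0, median 0.09, fry adjusted p = 0.412). Fcrls had 0.41, while P2ry12 (0.24), Tmem119 (0.13), Cx3cr1 (0.06) and Csf1r (0.01) had smaller values. The lysosome list was not past the threshold (12 of 23 above 0, median 0.02, fry adjusted p = 0.412); Cd68 passed adjusted over the list alone. Npc2, a cholesterol carrier of the lysosome, had 0.15.

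Trem2 itself was higher in the Grn knockout, 232 ± 29.3 against 143 ± 13.2, 1.61-fold, with no overlap between the groups (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 animals can give). In the fit over all 4 genotypes, which pools the spread with that of the near-background values in animals without Trem2, the SE was 0.39 and Trem2 did not pass (limma adjusted p = 0.926). With only these 2 groups in the fit it did (limma adjusted p = 0.0330). Of the 708 genes, 24 had groups without overlap, and 20.2 would be expected by chance (2.86%).

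Genes of other cell types were not past the threshold. In the oligodendrocyte and myelin list 19 of 20 members lay below 0, with a median of -0.15, but no member and not the list passed (fry adjusted p = 0.453); Mog had -0.23 and Mal, a myelin proteolipid, -0.25. Gfap, the astrocyte intermediate filament, measured 1081 ± 134 against 794 ± 187 (limma adjusted p = 0.726). Psmb8, of the immunoproteasome, had 0.28, the inflammatory protease Casp1 0.39, the endothelial receptor Tie1 -0.40 and the neuronal activity gene Npas4 -0.41, none past the threshold.

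Camera with a preset correlation called 5 lists: the 2 that passed with fry and (adjusted p) oligodendrocyte and myelin 0.00200, homeostatic microglia 0.00470, and lysosome 0.0471, of which the first lay on the low side. The medians and fry adjusted p of the remaining lists in this comparison were as follows. Reactive astrocyte genes had 0.05 (adjusted p = 0.951), astrocyte genes 0.01 (adjusted p = 0.983), and cytokine and innate signalling genes 0.07 (adjusted p = 0.951). Pan-neuronal genes had -0.05 (adjusted p = 0.951), glutamatergic synapse genes 0.02 (adjusted p = 0.954), dopamine and striatum genes -0.11 (adjusted p = 0.954) and immediate early genes -0.03 (adjusted p = 0.974). Endothelium and mural cell genes had -0.03 (adjusted p = 0.951) and cholesterol and lipid genes -0.03 (adjusted p = 0.983). The medians of the GABAergic (adjusted p = 0.972), autophagy (adjusted p = 0.951) and oxidative stress (adjusted p = 0.502) lists lay within 0.01 of 0, with means of 0.01, -0.03 and 0.11; in the GABAergic and autophagy lists the median and the mean differed in sign.

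Scaling to the positive controls moved the median of all genes by 0.35 and gave every gene the same SE, 0.32. That was wider than before for Cd68, C1qa and C1qb, whose calls ended. Relative to the median under that scaling their log2 fold changes were 0.81, 0.67 and 0.54. The calls of the complement and activated microglia lists ended too. C1qa lost its call without wild type replicate 3 (adjusted p = 0.0532), wild type replicate 4 (0.0690), Grn knockout replicate 2 (0.0762) or Grn knockout replicate 4 (0.0706), and C1qb with only these 2 groups in the fit (0.0979). Directions here and below are relative to the reference genes to which the values are scaled, and wild type had more negative control counts than the Grn knockout (17.3 against 12.4 per probe, without overlap), so that a run batch following genotype stays open.

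**Figure D2:**
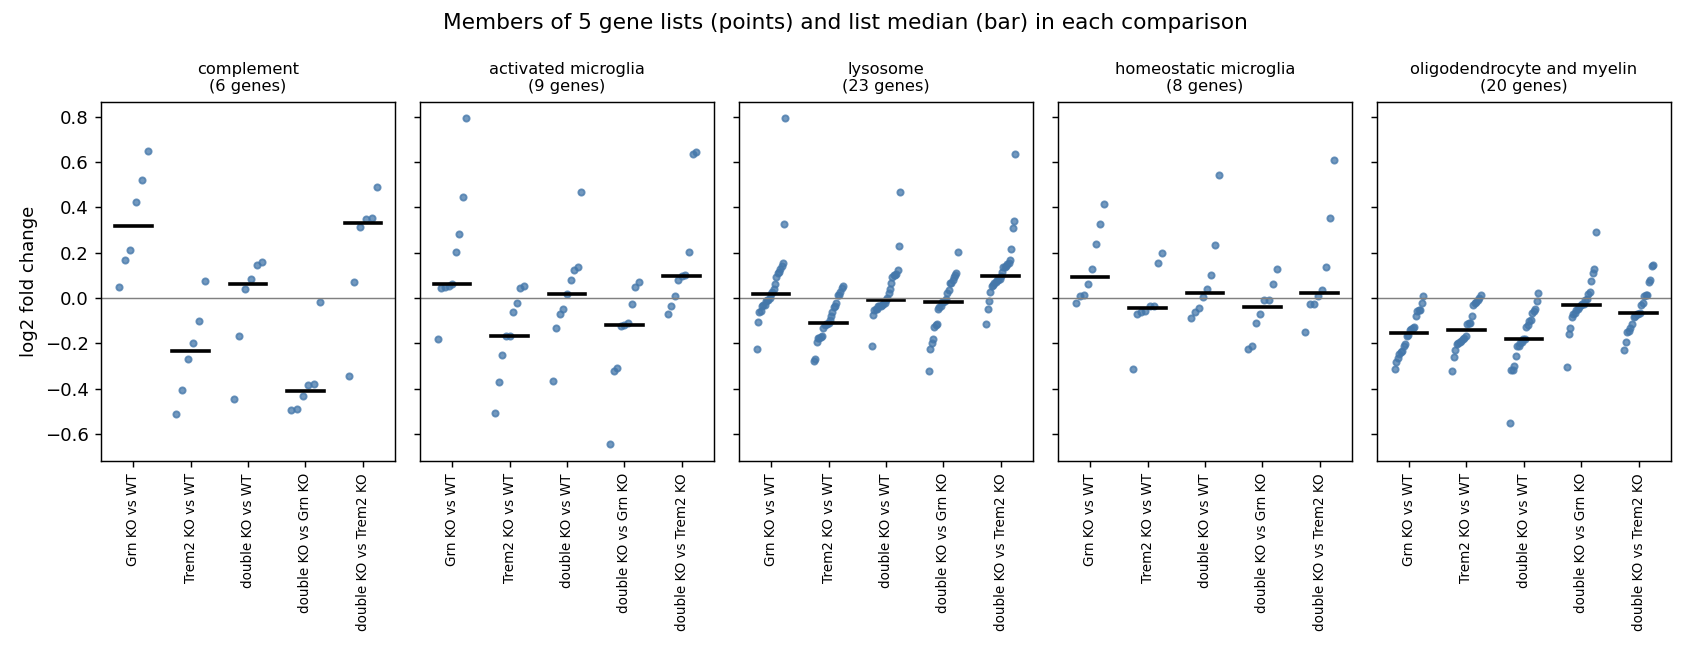
Log2 fold changes (vertical axis) of the tested members (points) of 5 gene lists in the 5 pairwise comparisons (horizontal axis), with the list median as a bar. The complement median was 0.32 for Grn knockout against wild type, 0.06 for double knockout against wild type and -0.41 for double against Grn knockout.

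The Trem2 knockout was set against wild type to measure the effect of TREM2 loss alone. Trem2 was the 1 gene past the threshold. Of the other genes, C1qb came nearest to it, on the low side. C1qb measured 571 ± 27.0 against 756 ± 43.9, with all 4 knockout animals below every wild type animal (log2 fold change -0.40, SE 0.08, limma adjusted p = 0.0698). C1qc had -0.27, C1qa -0.20 and C4a -0.51, each with a limma adjusted p of 0.804 or more.

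Apart from Trem2, 0 of 708 genes passed with limma, and 32 had an unadjusted p under 0.05; limma's voom on the recovered counts also called C1qb (0.0414). C1qb passed in 2 other settings (adjusted p = 0.0492 with a minimum mean of 50 and 0.0282 with a trended, robust variance) and without Grn knockout replicate 1 (0.0385) or replicate 4 (0.0293), and without Trem2 knockout replicate 4 the count was also 2 (Slc17a6, singled out after its value was seen, and Trem2). None of the 17 lists passed with fry, while camera with a preset correlation called 4, all on the low side (adjusted p: lysosome 0.0158, complement 0.0158, reactive astrocyte 0.0226, and oligodendrocyte and myelin 0.0226), and with an estimated one 0. Nearest with fry were the lysosome list (18 of 23 below 0, median -0.11, fry adjusted p = 0.0562), the complement list (5 of 6 below 0, median -0.23, adjusted p = 0.0882, with C1qb past the threshold adjusted over the list alone), the activated microglia list (7 of 9, -0.17, adjusted p = 0.0882), the reactive astrocyte list (9 of 10, -0.25, adjusted p = 0.0882) and the astrocyte list (median -0.11, adjusted p = 0.0882). The remaining lists reached adjusted p between 0.450 and 0.906.

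The lysosomal enzyme Gaa had a log2 fold change of -0.20 and Cd68 -0.17. Among innate immune genes, Tlr2 had -0.37, Cybb -0.51, the lectin Cd33 -0.31 and the chemokine receptor Cxcr4 -0.57. Tlr2 measured 16.3 to 17.3 in the Trem2 knockout animals other than replicate 1, below their background thresholds of 24.7 to 26.0. Wild type had more negative control counts than the Trem2 knockout (14.6 to 19.9 against 10.6 to 14.1 per probe), which can add to falls of weak genes. Homeostatic microglia genes lay near wild type (median -0.05), with P2ry12 at 0.20, Tmem119 at -0.06, Csf1r at -0.04 and Cx3cr1 at -0.06. Aldh1l1, a folate enzyme of astrocytes, measured 472 ± 76.0 against 588 ± 17.5 (-0.33), and Gfap had -0.32, Apoe -0.02. Mal had -0.32, Tie1 -0.35 and the synaptotagmin Syt7 0.16. The limma adjusted p of each gene in this paragraph was 0.804 or more. Grn measured 589 ± 34.0 against 617 ± 45.4 (two-sided exact permutation p = 0.371).

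The double knockout was set against wild type to see what remained of the response when both genes were lost. Grn and Trem2 were the 2 genes past the threshold. Cd68 measured 153 ± 13.6 against 111 ± 16.2, 1.38-fold, with all 4 animals above every wild type animal, but it did not pass (log2 fold change 0.47, SE 0.12, limma adjusted p = 0.121). C1qa (0.16) and C1qb (0.09) lay close to wild type, with 95% confidence intervals of -0.10 to 0.42 and -0.09 to 0.26.

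Apart from the knocked-out genes, 0 of 708 genes passed with limma, and 52 had an unadjusted p under 0.05; voom called Mal as well. Mal measured 1050.2 ± 43.1 against 1544 ± 115 (log2 fold change -0.55, SE 0.12, limma adjusted p = 0.0920), and Mog had -0.32 and Mag -0.30, the last 2 being adhesion proteins of myelin. In the oligodendrocyte and myelin list 19 of 20 members lay below 0 (median -0.18, fry adjusted p = 0.368). Endothelial Tie1 had -0.54 (limma adjusted p = 0.121) and Esam -0.30, in a list with 13 of 15 members below 0 (median -0.28, fry adjusted p = 0.313).

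Npas4, a transcription factor induced by neuronal activity, measured 73.6 ± 24.3 against 221 ± 90.7, with no overlap (log2 fold change -1.53, SE 0.40, limma adjusted p = 0.131), and the NMDA receptor subunit gene Grin2a 377 ± 41.9 against 282 ± 16.6 (limma adjusted p = 0.226). The microglial receptor Fcrls had 0.54 (limma adjusted p = 0.239), Casp1 0.47, P2ry12 0.23, Tmem119 -0.09, Csf1r -0.06, Cx3cr1 -0.05 and Apoe 0.08. On the low side were C3 (-0.45), the copper oxidase Cp (-0.46), the small heat shock protein Hspb1 (-0.58) and Gfap (-0.08). Adjusted over their lists alone, Cd68, Fcrls, Cp, Mal, Tie1 and Npas4 passed. None of the 17 lists passed with fry (camera with a preset correlation called 2, both on the low side, by adjusted p oligodendrocyte and myelin 0.00114, and endothelium and mural cells 0.00114; with an estimated one 0), with fry adjusted p from 0.313 to 0.997. The complement list had a median of 0.06 and a mean of -0.03 (adjusted p = 0.965), the activated microglia list a median of 0.02 (adjusted p = 0.828), and the lysosome list a median of -0.01 and a mean of 0.03 (adjusted p = 0.608).

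Quantile normalization raised the count to 8 genes (adding Cd68, Cers1, Fcrls, Hgf, Mal and Psmb9), and weighting the animals to 7 (adding Cd68, Gata2, Gdpd2, Mal and Tie1); Cers1, Hgf, Psmb9, Gata2 and Gdpd2 were singled out after their values were seen. The count was 6 without Grn knockout replicate 1, 5 without Grn knockout replicate 2 and 4 without wild type replicate 1.

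The double knockout was set against the Grn knockout to measure what TREM2 loss changes where progranulin is lacking. The complement list, led by the C1q chains, fell, and C1qb passed on its own. C1qb fell from 1090.3 ± 142 to 802 ± 21.0 (log2 fold change -0.43, SE 0.08, limma adjusted p = 0.0353), and all 4 double knockout animals lay below every Grn knockout animal. C1qa measured 595 ± 38.5 against 843 ± 117 (-0.49, limma adjusted p = 0.216) and C1qc 506 ± 51.7 against 660.0 ± 56.5 (-0.38, limma adjusted p = 0.309), also without overlap but not past the threshold. The complement list fell as a group, with 6 of 6 members below 0, a median of -0.41 and a fry adjusted p of 0.0127; C3 had -0.49 and C4a -0.38, and 3 members passed adjusted over the list alone.

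Cd68 measured 153 ± 13.6 against 192 ± 19.1 (log2 fold change -0.32, SE 0.12, limma adjusted p = 0.492). The activated microglia list did not pass (7 of 9 below 0, median -0.12, fry adjusted p = 0.0838). Tlr2, near background, had -0.65 and Apoe -0.12. The lysosome list lay near 0 (14 of 23 below, median -0.02, adjusted p = 0.646). Homeostatic microglia genes had a median of -0.04 (adjusted p = 0.646), with Tmem119 at -0.21, P2ry12 at -0.01, Cx3cr1 at -0.11 and Csf1r at -0.07.

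Reactive astrocyte genes were on the low side without passing (8 of 10 below 0, median -0.25, adjusted p = 0.109). Gfap measured 743 ± 109 against 1081 ± 134 (-0.54, limma adjusted p = 0.492), Cp had -0.52, Hspb1 -0.54 and the cytokine Tgfb1 -0.47; Cp and Tgfb1 passed adjusted over their lists alone. Mal had -0.30, Esam -0.29 and Npas4 -1.12, while Grin2a had 0.29 and the endocytic receptor Lrp1 0.20. Of 708 genes, 2 passed with limma (C1qb and Trem2) and 50 had an unadjusted p under 0.05. Camera with a preset correlation called 6 lists, all on the low side: complement and (adjusted p) cytokine and innate signalling 0.00144, reactive astrocyte 0.00144, endothelium and mural cells 0.00187, activated microglia 0.0120, and immediate early genes 0.0163. The 16 lists not past the threshold had fry adjusted p from 0.0838 to 0.789. C1qb passed in 15 of 29 other settings: it did not with only these 2 groups in the fit (adjusted p = 0.263), and with 1 animal left out it passed only when that was wild type replicate 1 or 4 or Grn knockout replicate 1 or 3, the other 12 giving 0.0504 to 0.195. The complement list lost its call without Grn knockout replicate 2 (fry adjusted p = 0.0507) or double knockout replicate 3 (0.0581), and with positive-control scaling (0.973), which also ended that of C1qb (adjusted p = 0.999) at a log2 fold change of -0.42 and an SE of 0.32.

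For the 3 genes that rose in the Grn knockout, the difference from wild type was set beside that of the double knockout. The double knockout log2 fold change against wild type was 59.1% of the Grn knockout value for Cd68, 24.1% for C1qa and 16.5% for C1qb, a median ratio of 0.241. With 1 animal left out the genes were chosen anew, so a shift in the median may come from a change in the genes called. The median was 0.449 without wild type replicate 1, where 5 genes, Grn included, were called. Where C1qa lost its call, the median was of Cd68 and C1qb alone. It was then 0.384 without wild type replicate 3 and 0.358 without wild type replicate 4. Likewise it was 0.413 without Grn knockout replicate 2 and 0.381 without Grn knockout replicate 4. The ratio also holds the effect of Trem2 loss, since the Trem2 knockout itself differed from wild type by -0.17 for Cd68, -0.20 for C1qa and -0.40 for C1qb. Grn loss where Trem2 is absent, the double against the Trem2 knockout, gave 0.64, 0.35 and 0.49, beside 0.79, 0.65 and 0.52 where it is present. Choosing the genes on the Grn knockout favours a larger value in that group, and choosing them on the double knockout left 0 genes. Of the 3, C1qb passed the direct test between the 2 knockouts.

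The double knockout was set against the Trem2 knockout to measure progranulin loss where TREM2 is already absent. Cd68 and C1qb rose, and so did the lysosome list as a group. Cd68 went from 98.3 ± 13 to 153 ± 13.6, 1.56-fold higher (log2 fold change 0.64, SE 0.12, limma adjusted p = 0.0142), and C1qb from 571 ± 27.0 to 802 ± 21.0, 1.40-fold higher (limma adjusted p = 0.00998). In both, all 4 double knockout animals exceeded every Trem2 knockout animal.

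The lysosome list rose with 20 of 23 members above 0, a median of 0.10 and a fry adjusted p of 0.00538; Cd68 was its 1 member past the threshold, also adjusted over the list alone. Gusb and Man2b1, hydrolases of glucuronides and mannosides, had 0.34 and 0.22, and Npc2 0.31, each with a limma adjusted p of 0.793 or more. Against wild type the same list had medians of -0.01 in the double knockout and -0.11 in the Trem2 knockout. The activated microglia list rose (7 of 9 above 0, median 0.10, fry adjusted p = 0.0411, and adjusted p = 0.173 with an estimated correlation). It lost its call without Cd68 and after recentring on the median or on the housekeeping list. It also lost it without any 1 of wild type replicates 3 and 4, Grn knockout replicate 1, Trem2 knockout replicates 2, 3 and 4 and double knockout replicates 1 and 4 (fry adjusted p from 0.0547 to 0.124). Cybb, near background, had 0.64, Cd9 0.20 and Apoe 0.10. The complement list passed narrowly (5 of 6 above 0, median 0.33, fry adjusted p = 0.0431; adjusted p = 0.173 with an estimated correlation). With 1 animal left out it passed only when that was Grn knockout replicate 2, 3 or 4 or Trem2 knockout replicate 1, the other 12 giving fry adjusted p from 0.0547 to 0.156, and another of the 35 splits of these 8 animals gave a lower fry p. Its members included C1qa at 0.35, C1qc at 0.31 and C4a at 0.35; 3 members passed adjusted over the list alone.

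Homeostatic microglia genes had a median of 0.02 (adjusted p = 0.489). Fcrls had 0.61 with no overlap (limma adjusted p = 0.329), and P2ry12 had 0.03, Tmem119 -0.03, Csf1r -0.03 and Cx3cr1 0.01. Immediate early genes had 8 of 9 members below 0 and a median of -0.38 without passing (fry adjusted p = 0.220); Npas4 measured 73.6 ± 24.3 against 219 ± 117 (-1.46, limma adjusted p = 0.329), and Npas4 and Fcrls passed adjusted over their lists alone. Psmb8 had 0.28, Gfap 0.25, Lrp1 0.18 and Grin2a 0.31. Of 708 genes, 3 passed with limma (Cd68, C1qb and Grn) and 39 had an unadjusted p under 0.05. Camera with a preset correlation called 5 lists, the 3 above and, on the low side (adjusted p), immediate early genes 5.16e-05, and endothelium and mural cells 0.0172. The 14 lists not past the threshold had fry adjusted p from 0.220 to 0.973. Scaling to the positive controls, which moved the median of all genes by 0.15, ended the calls of Cd68, C1qb and all 3 lists, with log2 fold changes of 0.79 for Cd68 and 0.64 for C1qb (0.62 and 0.48 relative to the median) and an SE of 0.32 for both, and without Trem2 knockout replicate 4 the count was 1, Grn (C1qb adjusted p = 0.0520). Cd68 also lost its call with only these 2 groups in the fit (adjusted p = 0.0537) and without Trem2 knockout replicate 1 (0.0571), Trem2 knockout replicate 3 (0.0621), Trem2 knockout replicate 4 (0.0581), double knockout replicate 1 (0.0680) or double knockout replicate 4 (0.0765).

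The interaction, which asks whether the effect of TREM2 loss differs with and without progranulin, gave 0 genes of 708 with limma, 24 with an unadjusted p under 0.05, and 0 with voom. Its values for the responding genes were -0.16 for Cd68 (95% confidence interval -0.50 to 0.19), -0.30 for C1qa (-0.66 to 0.07) and -0.03 for C1qb (-0.28 to 0.22), and C1qc had -0.11. Gfap had -0.22, Apoe -0.10, Npas4 -1.05, the proton pump subunit Atp6v0e2 0.38, the lysosomal disease gene Cln8 0.21 and the myelin lipid enzyme Fa2h 0.29, each with a limma adjusted p of 0.955 or more. None of the 17 lists passed with fry, and camera with a preset correlation called 1, on the low side (adjusted p: immediate early genes 0.00147), and with an estimated one 0 (fry adjusted p of 0.930 or more). The median SE of a log2 fold change was 0.16 for the interaction and 0.11 for a comparison of 2 groups.

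The genotypes overlapped on the first and second components of a principal component analysis of the tested genes without Grn and Trem2. The first component held 15.6% of the variance and the second 14.7%, and each genotype had animals on both sides of 0 on the first. On the third, with 13%, wild type animals scored 0.02 to 4.12 and double knockout animals -2.24 to -1.25, without overlap, and the single knockouts had animals on both sides of 0.

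**Figure D3:**
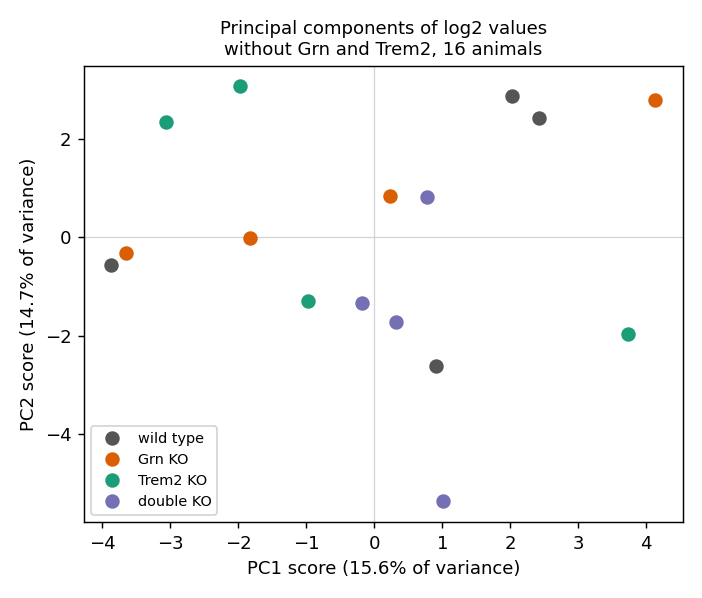
Scores of the 16 animals (points, coloured by genotype) on the first (horizontal axis) and second (vertical axis) principal components of log2 values without Grn and Trem2, with the percentage of variance on each axis. The 4 genotypes overlap.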

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

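The tests of technical explanations in this part were chosen only after the results were seen, whereas the comparison with other splits of the animals was planned. In 155 sets of 4 animals, 9 had 1 animal standing apart from the other 3, where chance at 1 in 20 gives 7.75. A set was a named gene, the total gene count, the negative control mean or the positive control sum in a genotype. Cd68 measured 220.39 in Grn knockout replicate 2 and 181 to 184 in the other animals of that genotype. In the same animal Mog measured 1145.39, against 873 to 915. Csf1r measured 476.79 in Grn knockout replicate 3, against 549 to 553, and Cln8 230.39 in Grn knockout replicate 4, against 205 to 208. Gfap measured 905.54 in double knockout replicate 1, against 681 to 695. In the Trem2 knockout, Cd33 measured 40.07 in replicate 4, against 35.4 to 35.9, and Tlr2 29.29 in replicate 1, against 16.3 to 17.3. In wild type, Npc2 measured 45.96 in replicate 2, against 64.9 to 68.4, and Syt7 1313.27 in replicate 3, against 1523 to 1564. Of the 62 genes too weak to be tested, 0 were above background in a knockout genotype only.

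Chance was weighed by exact enumeration of all 35 splits of the 8 animals of a comparison. A real split that ranks first, 1 of 35, is the smallest share this design can give. No adjustment was made over the comparisons and lists weighed, and those lists were the ones already called with fry. Ranking first therefore does not exclude chance. Genotype fixes the calls of the deleted genes, so the counts leave out Grn and Trem2. For Grn knockout against wild type the real split stood apart from every other: it gave 3 genes and the highest other gave 0 (1 of 35). The same held for its complement list (exact enumeration, directional fry p = 0.000519 against 0.00747 in the nearest other split, 1 of 35) and activated microglia list (0.00249 against 0.00844, 1 of 35). In Trem2 knockout and in double knockout against wild type 0 genes were left to weigh, and in the former another split called 3. For double against Trem2 knockout the real split also ranked first, but only with 2 genes against 1 (1 of 35). There the activated microglia list (0.00484 against 0.0360, 1 of 35) also stood apart from every other split, but the complement list did not, since another split gave 0.00386 against its 0.00761 (2 of 35). For the interaction 0 genes were called, so any split calls at least as many and the count cannot weigh chance. The highest of the 100 drawn splits called 2.

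The complement list was lower in the double than in the Grn knockout. For the list the real split ranked first (exact enumeration, directional fry p = 0.000747 against 0.00229 in the nearest other split, 1 of 35). By the count of genes it did not stand apart, since 1 other split also called 1 gene (2 of 35). That count does not ask which gene was called, so it does not weigh C1qb itself. Relative to the homeostatic microglia genes of each animal the list was still lower, by a log2 difference of -0.31 (two-sided exact permutation p = 0.0286, the smallest possible). That argues against fewer microglia as the whole cause only if those genes follow cell number, which was not measured. The tables argue against the reference-gene scaling (-0.37 relative to all tested genes, exact permutation p = 0.0286) and background (fry adjusted p = 0.00440 after subtraction of the negative controls). Cartridge and run day are not given and stay open beside the genotype. A lower C1q level without TREM2, whether or not progranulin is present, is 1 candidate, and a smaller C1q response to progranulin loss another: the log2 difference with Trem2 loss was -0.40 with and -0.43 without progranulin for C1qb (interaction -0.03, 95% confidence interval -0.28 to 0.22), and -0.20 and -0.49 for C1qa (interaction -0.30, -0.66 to 0.07).

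The lysosome list was higher in the double than in the Trem2 knockout, and the real split ranked first (exact enumeration, directional fry p = 0.000316 against 0.0275 in the nearest other split, 1 of 35). The tables argue against Cd68, its 1 tested member shared with the activated microglia list, as the whole cause (fry adjusted p = 0.0210 without it) and against the scaling (0.12 relative to all tested genes, exact permutation p = 0.0286). The difference may lie partly in a lower level in the Trem2 knockout: per animal, the lysosome mean was lower there than in wild type (log2 difference -0.10, exact permutation p = 0.0286), and the double knockout differed from wild type by 0.03 (exact permutation p = 0.200). As a list it did not pass against wild type in either (fry adjusted p = 0.0562 in the Trem2 and 0.608 in the double knockout). The genotype and an unrecorded run batch stay open.

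Trem2 transcript was higher in the Grn knockout than in wild type by a log2 difference of 0.69. The tables argue against the scaling (0.71 relative to all tested genes) and against background (0.80 after subtraction of the negative controls), each with a two-sided exact permutation p of 0.0286. Relative to the homeostatic microglia genes the difference was 0.54 (exact permutation p = 0.0286). That argues against more microglia as the whole cause only if those genes follow cell number, which was not measured. A candidate explanation is higher Trem2 expression per microglial cell without progranulin, which whole-brain RNA cannot show and which was not tested; an unrecorded run batch stays open too.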

How the results depend on the processing

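Scaling by the positive controls, voom and subtraction of the negative controls were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because the labels give no shared replicate numbers. DESeq2 was not run, since the table holds no raw counts of the genes as deposited. With genes chosen from the double knockout against wild type, the ratio of the double to the Grn knockout had no value, as 0 genes were called. Across 127 results for named genes, 3524 values under an alternative stayed on the same side of the threshold, 31 lost a call, 26 gained one, 62 uncalled values changed sign and 0 calls reversed. Weak genes are limited by background, and the interaction by its wider SE. Over the 29 alternatives the limma adjusted p in Grn knockout against wild type ran from 0.000615 to 0.130 for Cd68, 0.00196 to 0.315 for C1qa, 0.000615 to 0.543 for C1qb and 0.0330 to 0.9999 for Trem2. It ran from 0.0282 to 0.936 for C1qb in Trem2 knockout against wild type, from 0.00275 to 0.999 for C1qb in double against Grn knockout, and in double against Trem2 knockout from 0.00784 to 0.948 for Cd68 and 0.00288 to 0.948 for C1qb.

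Positive-control scaling moved the median of all genes by 0.35 for Grn knockout against wild type, 0.21 for Trem2 knockout against wild type, 0.36 for double knockout against wild type, 0.01 for double against Grn knockout, 0.15 for double against Trem2 knockout and -0.20 for the interaction. It gave 1 (Grn), 3 (Prl, Slc6a4 and Trem2), 4 (Grn, Nmb, Npas4 and Trem2), 1 (Trem2), 3 (Grn, Npas4 and Prl) and 1 (Prl) genes in that order. The SE of Cd68 went from 0.12 to 0.32. Limma's prior degrees of freedom were infinite in this setting, so all 703 genes took that SE in a comparison of 2 groups, 685 of them a larger and 18 a smaller one than before; its gene calls were made with that common SE, and the upper ends above, other than that of Trem2, come from it. The fry adjusted p became 0.373 for the activated microglia and 0.342 for the complement list in Grn knockout against wild type, 0.973 for the complement list in double against Grn knockout, and 0.714 for the lysosome, activated microglia and complement lists in double against Trem2 knockout. Prl, Slc6a4 and Nmb were singled out after their values were seen.

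For Trem2 knockout against wild type the count was 2, C1qb and Trem2, with a minimum mean of 50, a trended and robust variance, or voom. For double knockout against wild type it was 8 with quantile normalization and 7 with animal weights. For double against Grn knockout it was 1 with only the 2 groups fitted and 6 with animal weights (C1qa, C1qb, C1qc, Cp, Trem2 and Uchl1). Without shared members the activated microglia list had a fry adjusted p of 0.429 in Grn knockout against wild type and 0.220 in double against Trem2 knockout. In the latter it had 0.0753 after median recentring, 0.0733 after housekeeping recentring and 0.173 with camera's estimated correlation, and the complement list 0.0733 and 0.173 under the last 2. The other 4 list calls held with an estimated correlation. Camera with a preset correlation, which compares a list with the other genes, kept all 6 list calls and added others in every comparison. Where a fit held fewer groups or genes its residual degrees of freedom or adjustment changed; for the other alternatives the cause was not tested.

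With 1 animal left out, counts ran from 3 to 5 for Grn knockout against wild type, 1 to 2 for Trem2 knockout against wild type, 2 to 6 for double knockout against wild type, 1 to 3 for double against Grn knockout, 1 to 3 for double against Trem2 knockout and 0 to 0 for the interaction. The fry adjusted p in Grn knockout against wild type ran from 0.00901 to 0.0765 for the activated microglia and 0.00101 to 0.0388 for the complement list. In double against Grn knockout the complement list ran from 0.00167 to 0.0581. In double against Trem2 knockout the lysosome list ran from 0.00170 to 0.0247, the activated microglia list from 0.0177 to 0.124 and the complement list from 0.0132 to 0.156, both highest without double knockout replicate 4. The activated microglia list lost its call there without any 1 of wild type replicates 3 and 4, Grn knockout replicate 1, Trem2 knockout replicates 2, 3 and 4 and double knockout replicates 1 and 4. The complement list passed only without Grn knockout replicate 2, 3 or 4 or Trem2 knockout replicate 1. The median ratio of double to Grn knockout log2 fold changes against wild type ran from 0.197 to 0.449, highest without wild type replicate 1. Its genes were chosen anew in each fit, so the range is not that of 1 fixed set of genes.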

Other observations

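The averaged contrasts in this part, and the split counts without the deleted genes, were chosen after the data were seen. Averaged over both states of Trem2, 8 animals without Grn differed from 8 with it in 5 genes. Cd68 (log2 fold change 0.72), C1qb (0.50), C1qa (0.50) and C1qc (0.37) rose, with limma adjusted p of 8.11e-05, 8.11e-05, 0.00573 and 0.0295, and Grn fell. The complement, activated microglia and lysosome lists rose (fry adjusted p = 0.00113, 0.00113 and 0.00244; adjusted p = 0.0115 for each with an estimated correlation). The averaged lists were not tested without Cd68, which both the activated microglia and the lysosome list hold. In the separate comparisons the activated microglia list lost its call without Cd68. The lysosome list passed there only where Trem2 was absent. Of 100 drawn splits 1, the real one, called as many as its 4 genes other than Grn, and the highest other called 2, so such a count was rare by chance.

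Averaged over both states of Grn, 8 animals without Trem2 differed from 8 with it in 2 genes, C1qb, which fell (-0.42, limma adjusted p = 0.00117), and Trem2. The complement, activated microglia, reactive astrocyte and lysosome lists fell (medians -0.34, -0.14, -0.23 and -0.07; fry adjusted p = 0.00424, 0.0102, 0.0144 and 0.0385). None of these list calls held with an estimated correlation (adjusted p = 0.0504, 0.0504, 0.0504 and 0.174). Among the reactive astrocyte genes, Gfap, Cp and Hspb1 passed adjusted over the list alone, with -0.43, -0.39 and -0.40. Without the deleted Trem2, 13 of 100 drawn splits called as many genes as the real 1, the highest 11, so a count of 1 gene was not rare by chance. That count does not ask which gene was called, so it does not weigh C1qb itself.

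Lists too small for a list test had no gene past the threshold in any comparison, the lowest limma adjusted p being 0.295 for interferon and antigen presentation in double knockout vs wild type. For Grn knockout against wild type, the 4 interferon and antigen presentation genes ran from 0.05 to 0.28 in log2 fold change, the 2 oligodendrocyte precursor genes from 0.04 to 0.07 and the 3 peripheral leukocyte genes from -0.35 to 0.25.

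The effect of losing a gene was compared between separate animals across 706 genes, without Grn and Trem2; genes are not independent replicates, and no p is given. The Grn effect with Trem2 present and with Trem2 absent had a Pearson r of 0.183 and a Spearman rho of 0.0579, with the same sign in 48.6% of genes. The Trem2 effect with Grn present and with Grn absent had an r of 0.240 and a rho of 0.238, with the same sign in 58.6%.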
